A study of Tetranychus urticae with 5 samples.

How the data were processed

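RNA of deutonymph females of 3 strains of the spider mite Tetranychus urticae was compared on 5 Agilent arrays with 2 colours. Each array held a spirodiclofen-resistant strain in Cy5 and the reference strain LS-VL in Cy3, with 3 arrays for SR-VP and 2 for SR-TK, which the labels call biological replicates. The labels do not say whether LS-VL was extracted anew for each array, so p-values may leave out part of its spread. All 5 arrays lay on 1 slide and came from 1 scan, per the file headers.

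Per the file headers, the authors deposited the intensity of each spot as the scanner gave it, with a local background intensity and with processed intensities that were background-subtracted and dye-normalized within the array (linear and lowess). Agilent Feature Extraction 10.5 is named in the submitters' processing notes. The deposited log10 ratio of processed Cy5 over Cy3 served only as a check, and its correlation with the log2 ratios computed here ranged over arrays from 0.77 to 0.89 across spots. The authors also deposited a list of signed fold changes for each strain; how these were made is not given in the sources used here.

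The design fixed before the data were examined called for mean foreground signals. The columns read here held median foreground signals, so these were used with the median background, also in the alternative with no background correction; this departs from that design. Background was corrected by normexp with an offset of 50, followed by loess within arrays with control spots at weight 0 and Aquantile normalization between arrays, in limma 3.58.1 under R 4.3.3. Control spots and spots flagged as population or non-uniformity outliers were left out (874 spot values over the arrays). Saturated spots were not filtered. A probe was kept when it was well above background in the same channel on at least 2 arrays of a strain. This kept 75.6% of the spots that were not controls, and 44268 probes after names starting with Rep were left out. Up to 3 probes per gene were averaged, which gave 15861 genes.

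A gene is a name of the array's design, in the form of a scaffold and a number. Of the genes tested, 353 carry a symbol as a suffix, and symbols in the text come only from there; the RefSeq table matched none of the other names, so the files do not pair these with gene names. The array appears to hold 2 numberings. There, 331 suffixed names share their number with a plain name, yet their log2 ratios correlated across genes only by 0.15 to 0.24 per array, with no filter on signal. Probes of 1 gene correlated by 0.72 to 0.74. That range is from means over the 5 arrays, in genes with all 3 probes bright on every array, so the ranges are not strictly alike. A gene with a symbol may therefore be on the array again under a plain number and be counted more than once. Names starting with Rep, spotted 15 times each, were kept out of the gene test.

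limma fitted 1 coefficient per strain to all 5 arrays, so SR-TK borrows its spread largely from SR-VP (3 residual and 3.07 prior degrees of freedom). The tests were the mean log2 ratio of each strain against 0, and SR-TK minus SR-VP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1. Errors beside log2 ratios are limma's standard errors (SE), from 3 arrays for SR-VP and 2 for SR-TK. With LS-VL always in Cy3 and no dye swap, gene-specific dye bias and the spread of LS-VL are not separated from the strain effect; a dye bias common to all arrays cancels in SR-TK minus SR-VP. A gene with no probe well above background in a strain on any of its arrays has only a bound. The bound sets the mean signal of the bright strain against the mean, per array, of the dim signal or the lowest signal well above background in that channel, whichever is higher. It stays open to dye bias. Where the dim signal is the higher on every array, the bound equals the measured fold. That lowest signal is the minimum over all probes kept, so "at least" marks no strict detection limit.

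Of 30 gene lists fixed beforehand by description, the names on the array had members for 5. Lists of cytochrome P450s, carboxyl/cholinesterases (CCEs), glutathione S-transferases (GSTs) and ABC transporters were matched by the array's spelling of symbols, which was set, like the subfamilies, after the symbols were seen and before any test. The cuticle and nervous system lists matched 1 name each, under the 3 needed for a test, and those for yolk, males, gut and silk had no members, so stage and tissue makeup was not checked by them. camera used a preset correlation of 0.01 between genes and, as an alternative, an estimated one; fry was another, each with Benjamini-Hochberg adjustment over 15 lists and sublists per comparison. Fisher's exact test (two-sided) of called members against other genes was added after the calls were seen.

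The genes named were, per strain, the 10 highest and 10 lowest called genes with 1 direction on every array, the 5 largest differences each way between strains, up to 4 called members per list, acetyl-CoA carboxylase, CYP392E7 and CYP392E10. Of plain numbers, at most 2 that rose and 2 that fell are printed in the passage on each comparison. Genes with a symbol outside this rule were chosen after their values were seen. Alternatives chosen beforehand covered the processed signals, background correction, offset, centring, probe filters, probe summaries, fold threshold, arrays in the fit, array weights, separate channels, the replicate block and leaving out each array. In simulated data of 15861 genes with 200 changed in each strain, 96% of changes of 1.5 log2 units were recovered in SR-VP, 100% in SR-TK and 97% in the difference; changes of 1 log2 unit, at the threshold itself, were recovered for 38%, 54% and 54%. Changes of 2 and 3 log2 units were all recovered (100%) in each comparison, with 1, 1 and 3 false calls. Those data held no LS-VL deviation shared by arrays. Unchanged strains simulated with 1, given the spread of single arrays, had a mean of 46.8 false calls in SR-VP over 100 simulations. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.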

Results

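Spirodiclofen is an acaricide that inhibits acetyl-CoA carboxylase, the enzyme of the first committed step of fatty acid synthesis. SR-VP and SR-TK are strains of the spider mite Tetranychus urticae kept on bean under selection with 5000 and 1000 mg/L spirodiclofen, respectively, and LS-VL is the reference strain, grown alike without it. Transcript levels in deutonymph females were measured as the ratio of resistant strain (Cy5) to LS-VL (Cy3) on 3 arrays for SR-VP and 2 for SR-TK. Between 54.3% and 75.9% of spots were well above background in Cy5, and between 59.2% and 71.5% in Cy3. SR-VP replicate 3 stood apart, with the lowest share in both channels and a lower-quartile Cy5 signal of 168.5 against 78.5 to 82 on the other arrays. No spot was saturated. Log2 ratios correlated across genes by 0.66 to 0.81 between SR-VP arrays, by 0.59 between the SR-TK arrays and by 0.48 to 0.67 across strains.

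The first comparison asked which genes differ in level between SR-VP and LS-VL. The strongest rises among genes with a symbol were in cytochrome P450s of the CYP392E subfamily, a group of monooxygenases. CYP392E6 was 10.4-fold higher in SR-VP (log2 ratio 3.38 ± 0.09 SE, n = 3 arrays, adjusted p = 9.1e-05) and CYP392E8 was 10.05-fold higher (3.33 ± 0.08). CYP392E10 was 3.29-fold higher (1.72 ± 0.09) and CYP392E7 was 2.45-fold higher (1.29 ± 0.09). The study chose both from these arrays, so their direction is not independent evidence. The probes of CYP392E7 disagreed in direction in SR-VP (values given further below), so its fold is uncertain, which the SE over arrays does not show. The esterase TuCCE-51 was 7.15-fold lower (−2.84 ± 0.15).

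In total 310 of 15861 genes were called in SR-VP, 178 higher and 132 lower, and 29 of them carry a symbol. Of 100 P450s measured, 16 were higher, 1 was lower and 83 were not called, and the same numbers were called when adjusted over the list alone. The CYP392 family held 15 of the higher ones among its 43 measured members, with 9 of 20 in CYP392A and 5 of 10 in CYP392E, while none of 10 in CYP392D was called. Without SR-VP replicate 2, 9 P450s were higher, with 8 in CYP392, 3 in CYP392A and 5 in CYP392E, and 18 of the 29 genes with a symbol stayed called. Within CYP392A, CYP392A9v2 reached 1.24 ± 0.11 and CYP392A11 reached 1.21 ± 0.08. Outside CYP392, CYP385C2 was higher (1.36 ± 0.13), and a P450 given only as CYP was lower (−2.31 ± 0.24). By camera the P450 list, with a median log2 ratio of 0.04, shifted up in SR-VP (adjusted p = 0.00935), but not with an estimated correlation (p = 0.503, adjusted p = 0.838). The CYP392 list, with a median of 0.45, did likewise (adjusted p = 6.5e-06, and with an estimated correlation p = 0.241, adjusted p = 0.752). So did CYP392A (adjusted p = 1.1e-06; estimated-correlation p = 0.124), CYP392E (0.000885; p = 0.228) and CYP385 (0.00792; p = 0.251), the last not without SR-VP replicate 3 (adjusted p = 0.0591). P450s were called more often than other genes, 17% against 1.86% (Fisher's exact test, p = 8.8e-12), as were CCEs, 10.7% against 1.91% (p = 3.8e-05), and GSTs, 9.68% against 1.94% (p = 0.0222), though only 1 GST stayed called without SR-VP replicate 2. Fisher's test treats genes as independent, while the estimated correlation between genes was 0.30 in P450s, 0.16 in CCEs and 0.16 in GSTs. Its p-values here and for SR-TK below are therefore likely too small.

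CCEs, a family of ester-hydrolysing enzymes, went both ways in SR-VP. Of 84 measured, 6 were higher and 3 lower, also when adjusted over the list alone, and camera found no shift (adjusted p = 0.731). TuCCE-08 (1.64 ± 0.17), TuCCE-39 (1.54 ± 0.07) and TuCCE-60 (1.29 ± 0.07) were higher, and TuCCE-05 (−1.98 ± 0.11) and TuCCE-21 (−1.43 ± 0.14) were lower. TuCCE-04 was not well above background in LS-VL on any SR-VP array and was at least 3.45-fold higher in SR-VP (adjusted p = 0.0089); its call ended without any one of the SR-VP arrays (adjusted p = 0.058 without replicate 1). Among 31 GSTs, which conjugate glutathione to electrophiles, 3 were higher and none lower, also over the list alone. These were TuGSTinc03 (1.21 ± 0.18), TuGSTd06 (1.19 ± 0.13) and TuGSTd04 (1.03 ± 0.07), and camera found no shift of the list (adjusted p = 0.0687), though the sublist GSTd shifted up (adjusted p = 0.0256; estimated-correlation p = 0.241), except without SR-VP replicate 3 (adjusted p = 0.194). TuGSTinc03 lost its call without SR-VP replicate 2 (adjusted p = 0.075) or 3 (adjusted p = 0.069), and TuGSTd04 without replicate 2 (log2 ratio 0.99). None of 113 ABC transporters was called in SR-VP, though 6 higher and 4 lower ones passed the adjusted p alone, and camera gave an adjusted p of 0.771. No member of the sublists CYP389, GSTm, ABCC, ABCG and pABC was called in SR-VP.

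Acetyl-CoA carboxylase, under the symbol ACCase, had a log2 ratio of 0.37 ± 0.11 in SR-VP (adjusted p = 0.0887) and of 0.43 ± 0.14 in SR-TK (adjusted p = 0.116), so neither passed the test. Among genes with no symbol, Tetur01g05940 was the highest in SR-VP (4.08 ± 0.15) and Tetur32g00960 the lowest (−5.75 ± 0.44). The latter was well above background in SR-VP on only 1 of 3 arrays, and without replicate 3 its log2 ratio was −6.47, so its size is uncertain. With median centring in place of loess, the median of all genes moved to 0.12 in SR-VP, and 70.7% of its 430 calls were higher, against 57.4% of the 310. Without SR-VP replicate 3, 287 genes were called, of which 49.5% were higher.

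**Figure D1:**
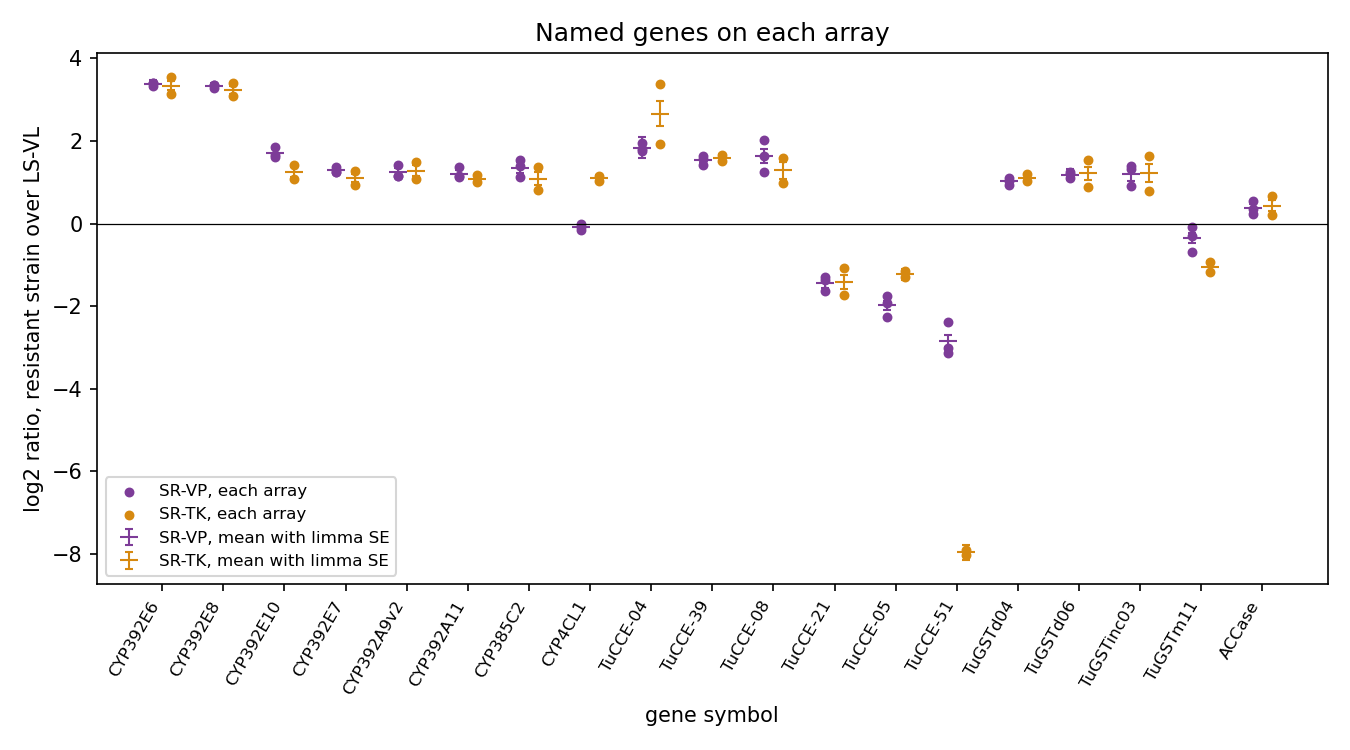
Log2 ratio of resistant strain over LS-VL (vertical axis) for genes with a symbol (horizontal axis); points are single arrays of SR-VP (3) and SR-TK (2), and bars with caps give the mean and limma's standard error. CYP392E6 and CYP392E8 lie above 3 in both strains, and TuCCE-51 lies at −2.84 in SR-VP and −7.97 in SR-TK.

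The second comparison asked the same of SR-TK. CYP392E6 and CYP392E8 were again the highest of the genes with a symbol, 10.1-fold (log2 ratio 3.34 ± 0.11 SE, n = 2 arrays, adjusted p = 0.00022) and 9.47-fold (3.24 ± 0.10) higher than in LS-VL. TuCCE-51 was 250-fold lower (−7.97 ± 0.18), with both channels well above background on both arrays. CYP392E10 (1.25 ± 0.11, 2.38-fold) and CYP392E7 (2.14-fold, SE 0.11 log2 units), chosen by the study from these arrays, were higher too, CYP392E7 not past the threshold without SR-TK replicate 1 (log2 ratio 0.92). The probes of CYP392E7 disagreed, with mean log2 ratios in SR-TK of −0.66, 1.27 and 2.69.

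In SR-TK 362 genes were called, 220 higher and 142 lower, and 31 carry a symbol. Of 100 P450s, 12 were higher and 1 lower, also over the list alone, among them 8 of 43 CYP392 members, with 5 of 10 in CYP392E and 2 of 20 in CYP392A. Without SR-TK replicate 1, 6 P450s were higher, with 5 in CYP392 and 3 in CYP392E, where 1 was lower, and 17 of the 31 genes with a symbol stayed called. Without replicate 2, 20 P450s were higher, with 13 in CYP392 and 7 in CYP392A. CYP392A9v2 (1.28 ± 0.13), CYP392B3 (1.26 ± 0.18) and CYP4CL1 (1.09 ± 0.08) were higher, CYP392B3 not past the threshold without SR-TK replicate 1 (0.87), and the P450 given as CYP that was lower in SR-VP was lower in SR-TK as well (−1.91 ± 0.30). By camera the P450 list shifted up (adjusted p = 0.0469), but not with an estimated correlation (p = 0.579, adjusted p = 0.956), nor without SR-TK replicate 1 (adjusted p = 0.756), SR-VP replicate 3 (0.256) or SR-VP replicate 1 (0.0523). The median log2 ratio in SR-TK was 0.06 for P450s and 0.23 for CYP392. By camera CYP392 (adjusted p = 0.00743, estimated-correlation p = 0.416), CYP392A (0.00214, p = 0.232) and CYP392E (0.0469, p = 0.394) shifted up too. CYP392 did not without SR-TK replicate 1 (adjusted p = 0.146) or SR-VP replicate 3 (0.103), and CYP392E kept its shift only without SR-TK replicate 2, with an adjusted p of up to 0.256 without the others. P450s were called more often than other genes, 13% against 2.21% (Fisher's exact test, p = 4.4e-07), as were CCEs, 16.7% against 2.21% (p = 6.1e-09), and GSTs, 12.9% against 2.26% (p = 0.00516), though without SR-TK replicate 1 only 1 GST was higher and 1 lower.

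Of 84 CCEs, 8 were higher and 6 lower in SR-TK, also over the list alone, and camera found no shift (adjusted p = 0.750). Without SR-TK replicate 1, 5 CCEs were higher and 5 lower, and without replicate 2 these were 10 and 4. TuCCE-39 (1.60 ± 0.09) and TuCCE-60 (1.35 ± 0.08) were higher, and TuCCE-21 (−1.41 ± 0.17) and TuCCE-05 (−1.23 ± 0.13) were lower. TuCCE-04 was 6.32-fold higher by the mean of its arrays (adjusted p = 0.0068), which lay at log2 ratios of 3.39 and 1.93. LS-VL was not well above background on either array. The bound equalled this measured fold, so it gives no lower limit, and without SR-TK replicate 1 the size was smaller. Of 31 GSTs, TuGSTinc03 (1.22 ± 0.22), TuGSTd06 (1.21 ± 0.15) and TuGSTd04 (1.11 ± 0.09) were higher and TuGSTm11 was lower (−1.06 ± 0.15), and camera found no shift of the list (adjusted p = 0.134). The GST sublist GSTd shifted up in SR-TK by camera (adjusted p = 0.00614), though not with an estimated correlation (p = 0.153, adjusted p = 0.942). Without SR-TK replicate 1, TuGSTm11 (log2 ratio −0.93), TuGSTd06 (0.89) and TuGSTinc03 (0.79) lost their calls, the last also without SR-VP replicate 2 or 3 (adjusted p = 0.054). None of 113 ABC transporters was called (3 higher and 1 lower without SR-TK replicate 1, and 3 lower without replicate 2), 4 higher and 1 lower one passed the adjusted p alone, and their median (0.03) and camera's direction (down, adjusted p = 0.885) differed in sign. Tetur01g05940 was again the highest of all genes (4.63 ± 0.19). Tetur30g01230 was the lowest (−7.99 ± 0.22), close to TuCCE-51. It may be the same gene under the other numbering, which was not tested. Tetur32g00960 was at least 60.1-fold lower. With only its own 2 arrays in the fit, SR-TK had 70 calls in place of 362, and 5 of the 31 genes with a symbol stayed called. With median centring, the median of all genes moved to 0.22, and 82.6% of 753 calls were higher, against 60.8% of the 362.

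**Figure D2:**
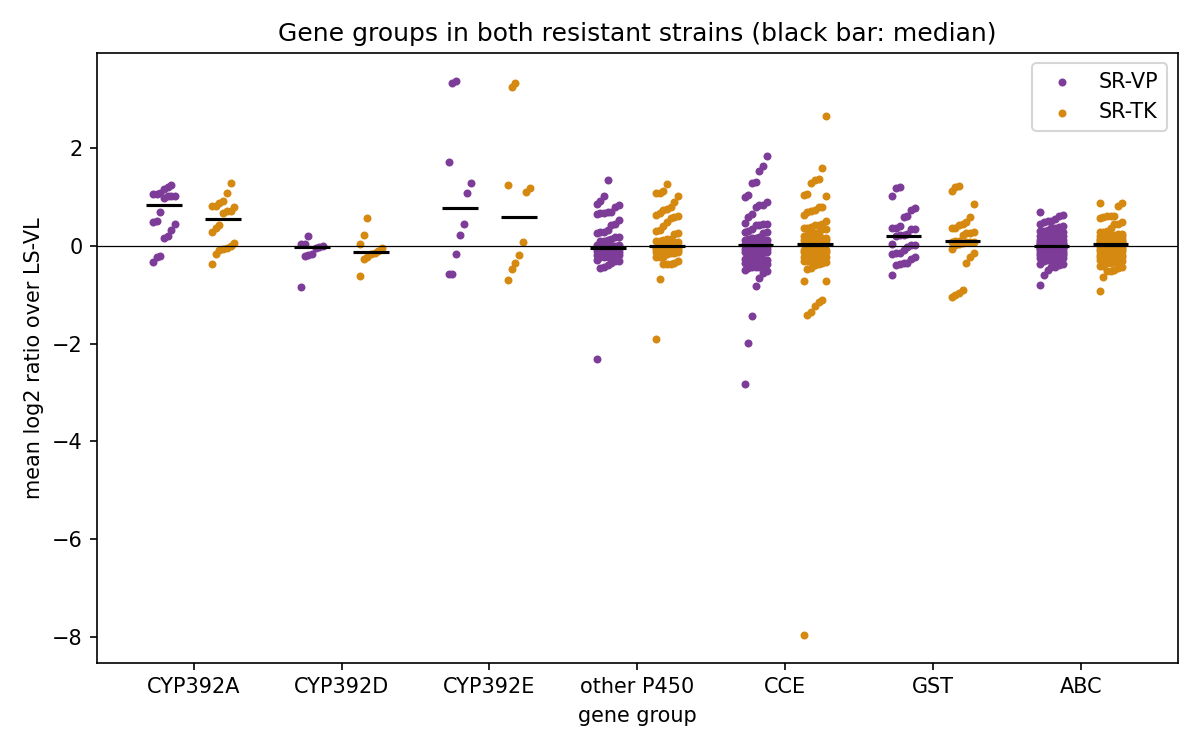
Mean log2 ratio over LS-VL (vertical axis) of each measured gene of a group (horizontal axis), for SR-VP and SR-TK, with the median as a black bar. The CYP392A median is 0.84 in SR-VP and 0.55 in SR-TK, the CYP392E medians are 0.77 and 0.59, and CCEs lie on both sides of 0.

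The strains were then compared with each other. TuCCE-51 was 35.0-fold lower in SR-TK than in SR-VP (log2 difference −5.13 ± 0.23 SE, adjusted p = 0.0044), and all 3 of its probes were lower. CYP4CL1, a P450, was 2.26-fold higher in SR-TK (1.17 ± 0.11, adjusted p = 0.028), at 1.09 in SR-TK against −0.08 in SR-VP. With an offset of 10 its log2 difference was 1.66, and with processed signals it was 2.25 and not called (adjusted p = 0.0537). With only probes above background everywhere CYP4CL1 was not measured, so its size is uncertain. TuCCE-51 and CYP4CL1 are the only 2 genes with a symbol among 34 that differed, 18 higher and 16 lower in SR-TK. With processed signals 2 were higher and 14 lower. Among the others, Tetur30g01230 had nearly the same log2 difference as TuCCE-51 (−5.10 ± 0.28, adjusted p = 0.0067). Tetur08g06880 went from −1.39 ± 0.07 in SR-VP to 0.95 ± 0.09 in SR-TK (adjusted p = 0.0044). Tetur09g00850 was at −0.14 ± 0.16 in SR-VP and at least 17.3-fold lower than LS-VL in SR-TK (adjusted p of the difference 0.0069). None of the 4 lists or their sublists differed between strains by camera; the smallest adjusted p was 0.0636, for CYP392 and CYP392A, which were lower in SR-TK. The count of 34 rests on every array, since leaving out any one left between 0 (without SR-VP replicate 3, where 1899 genes had an unadjusted p under 0.05 in limma) and 13 genes. On leaving out single arrays, TuCCE-51 lost its call only without SR-VP replicate 3 (adjusted p = 0.081), and CYP4CL1 lost it without any one array (adjusted p from 0.10 to 0.15).

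The calls of both strains overlapped. Of the genes called in SR-VP, 199 were called the same way in SR-TK, 120 higher and 79 lower, and 2 the opposite way; with median centring 75.5% of shared calls were higher, against 60.3%. They included CYP392E6, CYP392E8, CYP392E10, CYP392E7, TuCCE-39 and TuGSTd04. Independent lists of these sizes would share 2.47 higher and 1.18 lower genes. Both strains share LS-VL as control and the same dye orientation. Unchanged strains simulated against a shared LS-VL deviation, given the spread of single arrays, had 14.4 genes called the same way. The log2 ratios of the strains correlated across genes by 0.74, against 0.71 in that simulation, and their covariance was 0.096 against 0.036. These simulated values follow from the size set for the deviation, and its true size is unknown. They therefore cannot tell how much of the overlap the shared control gives. Genes are not independent replicates, and since LS-VL cannot be split here, part or all of the overlap may come from the shared control.

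**Figure D3:**
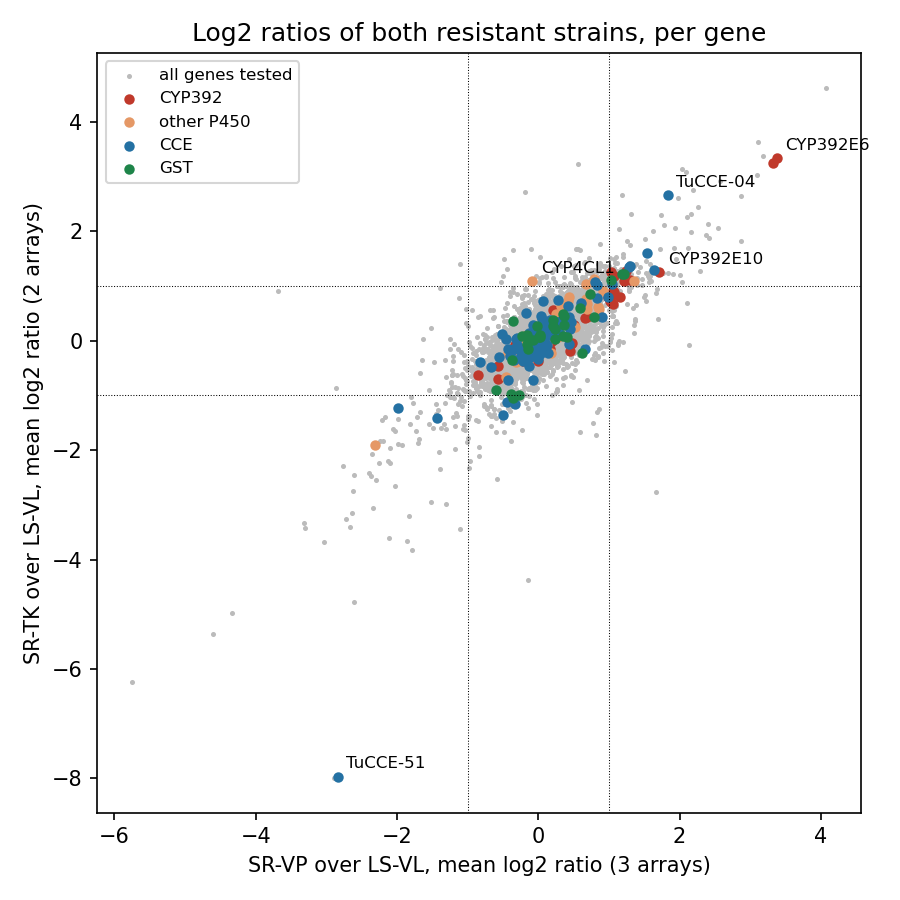
Mean log2 ratio of SR-TK over LS-VL (vertical axis) against that of SR-VP over LS-VL (horizontal axis) for 15861 genes, in grey, with P450s, CCEs and GSTs in colour and dotted lines at −1 and 1. Points run along the diagonal, with r = 0.74 across genes, and TuCCE-51 is among the points far below it.

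The authors' deposited table for SR-VP lists 546 genes with a fold change of at least 2, 329 higher and 217 lower, and the authors' deposited table for SR-TK lists 451, 234 higher and 217 lower. The authors' deposited tables have in common 184 genes, 179 of them in 1 direction. Log2 ratios at equal gene numbers in the authors' deposited tables and in the fit correlated across genes only by 0.24 and 0.22. Equal numbers were therefore not taken to name the same gene, and the authors' deposited tables were not compared gene by gene.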

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

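The test of single-probe variants, the test of dye orientation and the test of spot noise were chosen after the results were seen, as was the use of whole 95% intervals to judge the shares.

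The strains differed from each other in 34 genes, by the test of SR-TK minus SR-VP. Of these, TuCCE-51 (log2 difference −5.13) and CYP4CL1 (1.17) carry a symbol. By any probe on any array, 97.1% of the 34 genes were well above background in both channels in at least 1 strain. This lenient rule also passes a gene that is dim in the other strain, as Tetur09g00850 was in SR-TK, so it cannot rule out low signal there. Of the 18 genes still tested with only probes above background everywhere, 10 stayed called, and with processed signals 9 of the 34. A sequence variant of a strain under a single probe stays open for part of the set: of 31 genes with 3 probes, 25 (80.6%, Wilson 95% interval 63.7% to 90.8%) had all 3 past 0.5 log2 units in the direction of the difference, TuCCE-51 among them. CYP4CL1 fell short of this, with 1 probe at 0.41 in SR-TK and −0.08 in SR-VP. A strain difference in transcript level or in gene copies may account for the 25 genes and was not tested.

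The 199 genes called the same way in both strains raise the question of dye bias. Of 179 such genes with 3 probes, 156 (87.2%, Wilson 95% interval 81.5% to 91.3%) had all 3 past 0.5 log2 units the same way in both strains. This argues against bias of 1 single probe as the source of the call in those 156 genes, and leaves it open for the rest. The genes were picked by the mean of these same probes, which favours such agreement. A dye bias of whole transcripts, or a state of LS-VL, cannot be told apart from a change common to the resistant strains, because LS-VL was in Cy3 on all 5 arrays. A common response of resistant strains may thus be a candidate explanation, untested here.

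Probes of a called gene often disagreed. Of 277 genes called in SR-VP with 3 probes, 67 had probes more than 1 log2 unit apart, as CYP392E7 did (−0.84, 1.41 and 3.30 in SR-VP). Spot noise is argued against: deviations of probes from their gene mean in SR-VP correlated with those in SR-TK by 0.91 across probes. Compression of dim probes stays open, since the least changed probe was the dimmer in 58.2% of the genes (Wilson 95% interval 46.3% to 69.3%). Variants under probes or signal from related genes may also be a cause, and without probe sequences neither was tested.

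Outside the gene test, 1 of 155 names starting with Rep was called in each strain, the same one in both, at a log2 ratio of 1.88 ± 0.15 in SR-VP and 1.31 ± 0.18 in SR-TK. No group had the 4 samples needed to test for an outlying sample.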

How the results depend on the processing

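The slide-row block, the counts without suffixed names and the P450 lists without CYP392E6 and CYP392E8 were chosen after the data were seen. No called gene named here turned its direction. Over named genes and all settings other than leaving out an array, calls were kept 1632 times and lost 130 times. On leaving out an array they were kept 533 times and lost 92 times. With processed signals, offset 10 and no fold threshold, SR-VP had 629, 483 and 1792 calls, SR-TK 822, 565 and 1323, and the difference 16, 53 and 40; shared calls were 355 and 831 for the first and last. Median centring gave 753 calls in SR-TK, 77 in the difference and 322 shared. With only its own arrays SR-TK had 70 calls and shared 60. The difference had 11 genes with only probes above background everywhere, about 1.1e+02 with separate channels (56 higher and 49 lower) and 4 with the slide row as a block, where TuCCE-51 stayed called and CYP4CL1 did not (adjusted p = 0.0694). The cause was not tested. Leaving out suffixed names gave 278, 329 and 32 calls.

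With the replicate block, calls were 295 in SR-VP, 265 in SR-TK (13 of its 31 genes with a symbol stayed called), 148 shared and 2 in the difference. There, neither TuCCE-51 (log2 difference −5.22 ± 0.19 SE against −5.13 ± 0.23, adjusted p = 0.119) nor CYP4CL1 (1.14 ± 0.11 against 1.17 ± 0.11, adjusted p = 0.198) was called. Replicate numbers are shared by the strains for only 2 pairs, and the labels do not say that a number marks a shared batch. Deviations from the strain mean correlated across genes by 0.37 and 0.16 in these pairs, and by 0.16 between SR-VP replicate 3 and SR-TK replicate 2. Deviations of the 2 SR-TK arrays mirror each other, and those of the SR-VP arrays cancel in sum. These correlations are therefore not independent of each other and cannot decide the pairing. The log2 ratios of the 2 pairs correlated by 0.67 and 0.66, against 0.48 to 0.62 for other pairs across strains. Pairing by number thus stays open, and the main fit did not use it. Leaving out each array gave 255 to 315 calls in SR-VP, 328 to 408 in SR-TK, 0 to 13 in the difference and 156 to 184 shared. A strain left with 1 array is assumed to vary like the other.

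The camera adjusted p of P450s in SR-VP was 0.106 with the replicate block, 0.0548 with the slide row, and 0.838 with an estimated correlation; fry, which tests a list against no change and not against other genes, gave 0.0933. In SR-TK it was 0.196 with processed signals, 0.0673 with offset 10, 0.176 with median centring, 0.0704 with the median over probes, 0.057 with array weights, 0.341 with the replicate block, 0.108 with the slide row, 0.956 with an estimated correlation and 0.139 without CYP392E6 and CYP392E8; fry gave 0.192. By fry, adjusted p-values in SR-VP were 0.0345 for CYP392 and CYP392A, 0.0157 for CYP392E, 0.0464 for GSTd and 0.067 for CYP385. In SR-TK they were 0.111 for CYP392, CYP392A and GSTd, 0.0488 for CYP392E and 0.142 for CYP385. By camera, GSTs passed in SR-VP with median centring (0.00657) and probes above background everywhere (0.0234), and in SR-TK with median centring (0.00829). Leaving out each array gave P450s 0.00379 to 0.0444 in SR-VP and 7.72e-07 to 0.756 in SR-TK, and GSTs 0.0184 to 0.341 and 0.0199 to 0.372. A block of slide or scan was not run, since there is 1 of each.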

Other observations

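No test in this part was chosen after its result was seen, but the genes of the first paragraph were. Among P450s that make the moulting hormone of arthropods, 4 were not called in either strain, as most genes were not: CYP302A1 was at −0.23 ± 0.09 SE in SR-VP and −0.13 ± 0.11 in SR-TK, CYP307A1 at −0.14 ± 0.10 and −0.12 ± 0.12, CYP314A1 at −0.23 ± 0.12 and −0.02 ± 0.15, and CYP315A1 at 0.26 ± 0.16 and 0.49 ± 0.20. Of single genes for targets of other acaricides, not called either, the voltage-gated sodium channel VGSC was at 0.05 ± 0.07 and −0.20 ± 0.09, the receptor GABA2 at −0.01 ± 0.07 and 0.08 ± 0.08, and the acetylcholinesterase TuCCE-41-AChE at 0.12 ± 0.09 and 0.26 ± 0.11.

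Genes called in SR-VP were tested for lying next to each other in gene number, over 15496 names without a suffix. Of 278 called, 43 pairs of neighbours on a scaffold were called the same way, against a mean of 2.46 and a highest of 10 in 10000 shuffles; SR-TK had 48, against 3.51 and 12. This is consistent with clusters of neighbouring genes, as tandem copies or shared regulation might give, and probes that read related copies alike could give the same.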
